A study of Mus musculus with 59 samples.

How the data were processed

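RNA sequencing of the prefrontal cortex of C57BL/6J mice at postnatal day 25 was re-analysed from the deposited table. Mice heterozygous for Ash1l (HT) and wild-type mice (WT) of both sexes had received vehicle, fluoxetine or lithium through the mother's milk from postnatal day 3 to 24. The 59 libraries made 12 groups of 5, except HT lithium females with 4. Ash1l encodes a histone methyltransferase. Libraries were prepared with a stranded mRNA kit that selects polyadenylated RNA, so messages without a poly(A) tail were not measured.

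Per the labels, the authors used Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the genome build GRCm38, without the role or order of each. The deposited table holds 1 signal per gene and library, a read count divided by the library's size factor; the authors state no log or other transformation, and the values showed none. The gene annotation, the strand setting and the rule by which the table's 18088 genes were chosen are not given in the sources used here. In every library, dividing the values by its smallest step gave whole numbers within a tolerance of 0.01 for 100% of the values, so the read counts were recovered. They summed to between 24.47 and 36.32 M reads per library (median 27.98 M). Of the genes, 1 was at 0 in all libraries, and the others reached at least 9 reads in some library. Symbols were matched by gene identifier for 18077 genes, and positions came from GENCODE M21 on GRCm38. Reads of polymerase chain reaction copies without molecular identifiers are not independent molecules, and no share of counts in a single library is reported.

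A gene was tested if its normalised count reached 10 in at least 5 libraries, which kept 17875 genes and left out 213. The test was limma 3.58.1 with a mean-variance trend and robust variances on log2(normalised count + 1), in R 4.3.3, fitted once to all 59 libraries with 1 mean per group. The design fixed before the data were examined named edgeR for read counts and limma for values already normalised, and the limma branch was used. P-values were adjusted by Benjamini-Hochberg over all genes tested within each comparison, with a threshold of 0.05, and are from this test unless another tool is named. Errors beside log2 fold changes are standard errors. The comparisons were genotype within vehicle of each sex, each drug against vehicle within each genotype and sex, averages of these with equal weight for each stratum, and interactions. All comparisons with a drug used the same vehicle libraries, 5 per genotype and sex. Litters and dams were not labelled although the drug went through the mother, so p-values measure only the spread between these samples, and litter, cage and dam effects were not separable from treatment. The number in a library's title was not used to pair libraries. For the same number in different groups the mean correlation of residuals was -0.0112, against 0.0028 for different numbers. For HT lithium female replicate 4 the library name carries the number 5, and with it the values were -0.0129 and 0.00322.

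Genes named in the text were chosen by a rule fixed before the data were examined. They were Ash1l; up to 10 higher and 10 lower genes with the smallest p-values among those past the threshold, leaving out predicted and unnamed genes; members of the gene lists that passed over all genes or over the list alone; up to 6 genes per interaction; and 5 genes of the sex check. Where fewer than 3 genes passed, the 3 with the smallest p-values are given with values only. For genes chosen by p-value, the number of libraries on the side of the change comes from the same libraries and is not independent support.

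Gene lists were 37, written from general knowledge before the data were examined, and cover cell types and neighbouring brain regions, signalling and metabolic pathways, and responses to stress, activity and drugs. Some genes are in more than 1 list. Each was tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 37 lists and 14 comparisons together. Of 158 list tests past the threshold, 2 stayed past it with an estimated correlation, both in the comparison of the sexes, so each other list test is given with both values. Exact permutation tests of list means between groups of libraries were added later. Of 19 striatal markers 14 had a normalised count of at least 10 in every library and 2 are in another list, and of 18 choroid plexus markers 3 and 1.

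The tests were tried on simulated data with 50 changed genes per size of effect. In the comparison of HT with WT vehicle females, limma recovered 21 at 1.25-fold, 38 at 1.5-fold and 50 at 2-fold, with 4 false calls; for the fluoxetine average it recovered 42, 49 and 50, with 12 false calls. A simulated trend with GC content gave 3040 false calls, and 5 after the trend was removed. Each gene was drawn independently and no library was made to stand out, so these false calls are not the error rate in the real data. Other splits of the real vehicle female libraries called up to 1604 genes.

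The alternatives were TMM scaling, a pseudocount of 10, no filter, the replicate number as a block, library weights, a fit of only the groups compared, and leaving out each library. edgeR 4.0.16, DESeq2 1.42.0, leaving out the 2 libraries with a weight under 0.2 in the fit, removal of trends with GC content and gene length, and covariates for tissue of neighbouring regions were added after the data were seen. The values of 3 genes are not reported here.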

Results

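Ash1l itself was lower in the heterozygous mice. Across the 6 drug and sex strata, the average log2 fold change of Ash1l (ENSMUSG00000028053, chromosome 3, 88950622 to 89079375, plus strand) in HT against WT was -0.31 ± 0.023 (limma, adjusted p = 6.49e-15). Its normalised read count lay between 3641 and 4382 in all 29 HT libraries, and between 4703 and 6218 in 29 WT libraries. In the library labelled WT vehicle female replicate 3 it was 3557. Within vehicle males Ash1l fell by 0.40 on the log2 scale (± 0.056, adjusted p = 3.67e-05). Within vehicle females the value was -0.11 ± 0.056 (adjusted p = 0.21), and -0.20 (adjusted p = 0.00977) without WT vehicle female replicate 3 and WT vehicle male replicate 2; it ranged from -0.30 to -0.08 over the alternatives and single libraries left out.

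**Figure D1:**
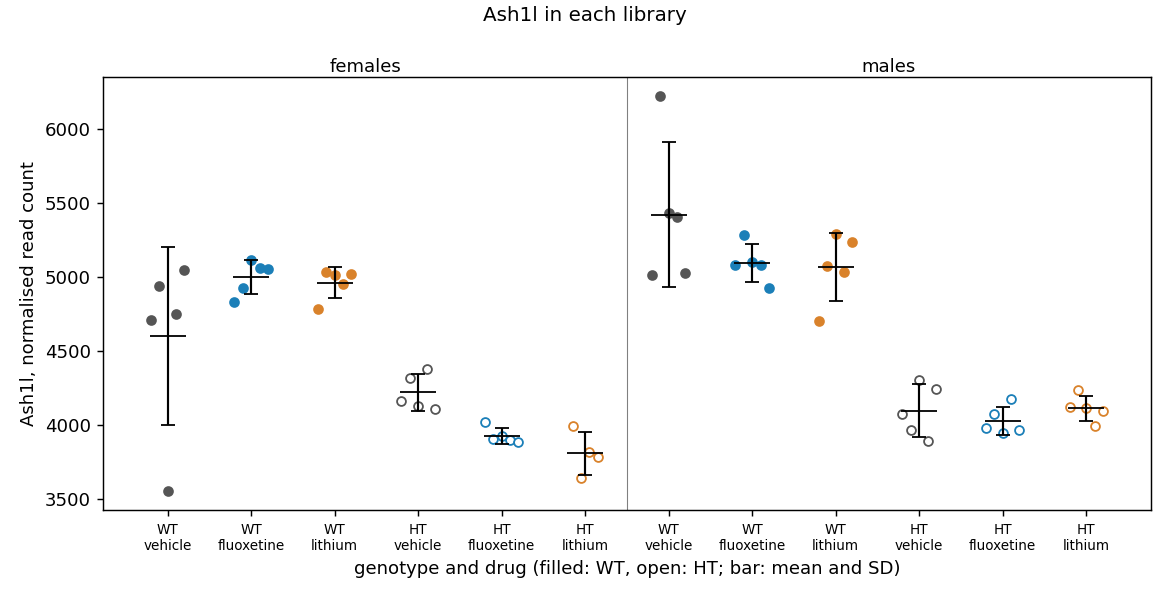
Normalised read count of Ash1l in each of the 59 libraries, by genotype, drug and sex, with the mean and SD of each group. HT libraries lie between 3641 and 4382, and WT libraries between 4703 and 6218 except WT vehicle female replicate 3 at 3557.

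The labels of sex matched the Y-linked genes and Xist, the RNA that silences an X chromosome, in 29 of 29 female and 30 of 30 male libraries. Averaged over genotypes and drugs, 14 genes were higher and 7 lower in females (limma, threshold 0.05). Xist was higher by 12.7 ± 0.18 on the log2 scale, and Ddx3y (-10.1), Eif2s3y (-9.57), Kdm5d (-9.36), Uty (-8.38) and Uba1y (-4.04) were lower. The X-linked Eif2s3x (0.55), Jpx (0.38), Kdm6a (0.30), Ddx3x (0.29) and Kdm5c (0.28) were higher in females, and all 5 have been described as escaping X inactivation. Of the list of 9 such genes, 6 rose over all genes tested and 7 adjusted over the list alone (camera, adjusted p = 8.56e-36; 1.26e-08 with an estimated correlation). Of the sex-check list, 1 rose and 4 fell over all genes and adjusted over the list alone (camera, adjusted p = 3.32e-57; 6.68e-15 with an estimated correlation). The immunoglobulin gene Ighm (0.43) and the lymphocyte gene Lag3 (0.27) rose, and Iqgap2 (-0.27) fell; the calls of Lag3 and Iqgap2 ended with the GC content and length trend removed. Markers of microglia were higher as a list of 18 (camera, adjusted p = 2.43e-09; adjusted p = 0.373 with an estimated correlation), with no member past the threshold over all genes and 9 risen adjusted over the list alone. The log2 fold changes had a Spearman correlation with GC content of 0.372 across genes, and genes are not independent replicates. The count of 21 became 38 without HT fluoxetine male replicate 2.

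Averaged over the drug and sex strata, 64 genes differed between HT and WT mice. Skida1 (ENSMUSG00000054074, chromosome 2, 18040676 to 18049051) fell by 0.31 ± 0.032 on the log2 scale (adjusted p = 1.48e-09). Met, which encodes the receptor of hepatocyte growth factor, fell by 0.42 ± 0.059 (adjusted p = 1.11e-05). Tbx1, a T-box transcription factor (ENSMUSG00000009097, chromosome 16, 18580979 to 18590671), fell by 1.98 ± 0.31 (adjusted p = 0.000167) at mean normalised counts of 9.26 to 15.5 in the HT groups and 31.0 to 46.0 in the WT groups (-1.56 with edgeR, -1.57 with DESeq2 and -1.14 with a pseudocount of 10, as 7 HT libraries had 0 or 1 reads of Tbx1), and the proneural factor Neurog2 by 0.62 ± 0.12 (adjusted p = 0.00273). The metallothionein genes Mt2 (-0.30) and Mt1 (-0.22) fell, as did Aldh1a1 (-0.28), which makes retinoic acid, the chemokine gene Cxcl14 (-0.14), the protease gene Pappa2 (-0.58), and Tchh (-0.34). Among genes that rose were Trp53i11 (ENSMUSG00000068735, chromosome 2, 93187548 to 93201759; 0.24 ± 0.036, adjusted p = 4.87e-05), the transcriptional regulator Lmo1 (0.26), Ndp (0.24), which encodes a Wnt receptor ligand, the cytokine gene Il33 (0.29), and Bok (0.26) of the Bcl2 family. Sgsm1 (0.15), Rhbdl3 (0.23), BC064078 (0.60), Banp (0.15) and the sodium channel subunit gene Scn3b (0.14) rose too, and Kdm2b, a histone demethylase gene, rose by 0.11. In all, 23 genes rose and 41 fell (limma, 29 HT against 30 WT libraries). Skida1, Tbx1 and Trp53i11 were on the side of their average in 29 of 29 HT libraries against the WT mean of the same drug and sex, and Met and Neurog2 in 27 of 29. The alternatives kept Skida1, Met, Tbx1, Mt2, Neurog2 and Trp53i11 past the threshold.

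The glucocorticoid-responsive list was lower on average in HT mice, which rested on females given fluoxetine (difference of list means -0.472; mean of the 6 strata -0.106, and -0.0327 without that stratum). Of its 20 members, Mt2, Mt1 and Tsc22d3 (-0.17), a classical glucocorticoid target, fell over all genes tested, and 5 fell adjusted over the list alone (camera, adjusted p = 8.4e-08; adjusted p = 0.375 with an estimated correlation). Among the genes of cholesterol synthesis, Insig1 (-0.14), which restrains the pathway, was the 1 member that fell over all genes, and 4 of 25 fell adjusted over the list alone (camera, adjusted p = 3.6e-07; adjusted p = 0.451 with an estimated correlation). The unfolded protein list was higher (camera, adjusted p = 0.000814; adjusted p = 0.57 with an estimated correlation), with no member past the threshold over all genes, and 5 risen and 1 fallen adjusted over the list alone. Immediate early genes, which neuronal activity induces, were higher as a list with a median log2 fold change of 0.12 (camera, adjusted p = 8.89e-07; adjusted p = 0.57 with an estimated correlation), and none of the 32 passed either way. This too rested on females given fluoxetine (difference of list means 0.876; mean of the 6 strata 0.131, and -0.0182 without that stratum). Interferon genes were higher (camera, adjusted p = 9.72e-05; adjusted p = 0.582 with an estimated correlation) and astrocyte markers lower (camera, adjusted p = 0.00051; adjusted p = 0.451 with an estimated correlation), with no member of either past the threshold over all genes. The chromatin list was higher (camera, adjusted p = 0.0192; adjusted p = 0.769 with an estimated correlation), with Kdm2b its 1 risen member over all genes and adjusted over the list alone. Markers of the striatum, which borders the dissected tissue, were lower (camera, adjusted p = 0.00712; adjusted p = 0.873 with an estimated correlation) with none passing. The difference of means of the chromatin list went from 0.0217 to -0.00316 without females given fluoxetine, that of the striatal markers from -0.202 to -0.0301 without males given fluoxetine, and those of the interferon and cholesterol genes from 0.0965 to 0.0485 and from -0.0526 to -0.0209 without the same males.

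In vehicle females, 1109 genes differed between HT and WT mice. Pcmtd2 (0.48 ± 0.077, adjusted p = 0.00127), the chromosome-silencing gene Smchd1 (0.46), Alg10b (0.48), the demethylase-family gene Jmjd1c (0.41), Pgap1 (0.71) and Senp7 (0.50) rose. So did the synaptic adhesion gene Il1rapl1 (0.63), the potassium channel gene Kcnd2 (0.41), Dmxl1 (0.52) and Rab8b (0.40). Plcd3 (-0.59 ± 0.11, adjusted p = 0.00366), Selenow (-0.40), Nudt18 (-0.37), Rbfa (-0.42), Nagk (-0.29), Syt3 (-0.45), Polr2e (-0.34), Rex1bd (-0.41), Ccdc124 (-0.50) and Cnpy3 (-0.27) fell. Each of these 20 genes was on the side of its change in 5 of 5 HT libraries against the WT mean, which their choice by p-value favours. In all, 811 genes rose and 298 fell (limma, 5 against 5).

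Of 61 cytosolic ribosomal genes in these females, 8 fell, among them Rpl37 (-0.42) and Rps21 (-0.34), and 32 adjusted over the list alone (camera, adjusted p = 1.49e-17; adjusted p = 0.504 with an estimated correlation). Of 67 genes of oxidative phosphorylation 11 fell, among them Atp5d (-0.39), Uqcr11 (-0.35) and Cox6b1 (-0.27), and 28 adjusted over the list alone (camera, adjusted p = 3.39e-12; adjusted p = 0.57 with an estimated correlation). Autism risk genes were higher, with 11 of 50 risen, among them Kmt2c (0.39), Gria2 (0.44), Fmr1 (0.39) and Adnp (0.54), and 20 adjusted over the list alone (camera, adjusted p = 4.32e-09; adjusted p = 0.451 with an estimated correlation). Of the 31 genes of the chromatin list, 7 rose, among them Kmt2c, Kdm6a (0.29) and the polycomb gene Suz12 (0.48), and 13 rose and 1 fell adjusted over the list alone (camera, adjusted p = 3.04e-05; adjusted p = 0.464 with an estimated correlation). Of the genes of GABA receptors, 4 rose, among them Gabra5 (0.56) and Gphn (0.24), and 9 adjusted over the list alone (camera, adjusted p = 0.0112; adjusted p = 0.629 with an estimated correlation). Endothelial markers were lower, with Bsg (-0.25) and Cldn5 (-0.40) fallen over all genes and 4 adjusted over the list alone (camera, adjusted p = 6.14e-05; adjusted p = 0.517 with an estimated correlation). Olfactory bulb markers were higher with a median of 0.93 and Synpr (0.97) the 1 risen over all genes and adjusted over the list alone (camera, adjusted p = 0.00864; adjusted p = 0.852 with an estimated correlation). Markers of oligodendrocytes (camera, adjusted p = 1.16e-05; adjusted p = 0.796 with an estimated correlation) and of microglia (adjusted p = 0.00351; adjusted p = 0.692 with an estimated correlation) were lower with none passing, as were mitochondrially encoded genes (adjusted p = 0.0188; adjusted p = 0.791 with an estimated correlation). These log2 fold changes had a Spearman correlation of -0.52 with GC content and 0.294 with gene length across genes. After the trends with GC content and length were removed, 7 genes were called, 4 of them among the 1109, and of the genes named above Pcmtd2, Smchd1 and Alg10b passed.

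The count rested on single libraries. It was 20 without WT vehicle female replicate 3, of which 18 were among the 1109, and 143 without HT vehicle female replicate 4, 246 without HT vehicle female replicate 2 and 2151 without HT vehicle female replicate 5. A limma fit of these 10 libraries alone called 0, with 2964 at an unadjusted p under 0.05. Over all libraries edgeR called 999 and DESeq2 1701.

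In vehicle males, Ash1l was the 1 gene that passed. Skida1 (-0.38 ± 0.077, adjusted p = 0.0684) and Ndufaf5 (0.29 ± 0.068, adjusted p = 0.294) had the next smallest p-values, and 1240 genes had an unadjusted p under 0.05. edgeR called 1 gene and DESeq2 2, and limma called 2 without HT vehicle male replicate 2 or 4. A limma fit of these 10 libraries alone called 0, with 657 at an unadjusted p under 0.05 and Ash1l at an adjusted p of 0.814, against 1.11e-09 to 0.000815 over the other alternatives. Genes of oxidative phosphorylation (camera, adjusted p = 1.38e-19) and ribosomal genes (adjusted p = 3.69e-19) were higher as lists. The chromatin list was lower (adjusted p = 1.69e-05). With an estimated correlation each adjusted p was 0.451, and no member passed over all genes or adjusted over the list alone. The autism list was lower (adjusted p = 1.1e-06; adjusted p = 0.588 with an estimated correlation), with Ash1l its 1 fallen member over all genes and adjusted over the list alone. For the ribosomal list, WT vehicle male replicate 2 stood at 10.71, against 11.04 to 11.11 in the others of its group. The log2 fold changes had a Spearman correlation with GC content of 0.219 across genes, of the other sign than in females.

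The genotype by sex interaction in vehicle mice was tested as a difference. It was higher in females for Kdm6a (0.50 ± 0.095), Zbtb6 (0.73), Jmjd1c (0.54) and Pcmtd2 (0.54), and lower for Mtch1 (-0.46) and Cnpy3 (-0.42), each with adjusted p = 0.0247 (limma); for Ash1l it was 0.29 ± 0.079 (adjusted p = 0.0367). In all, 316 genes had a positive and 203 a negative interaction. With WT vehicle female replicate 3 and WT vehicle male replicate 2 left out, or with the trends of GC content and length removed, limma called 0 (2215 and 1808 at an unadjusted p under 0.05); edgeR called 500 and DESeq2 1196 on all libraries, and 3677 had an unadjusted p under 0.05. Leaving out 1 library gave 0 without HT vehicle female replicate 4, WT vehicle female replicate 3, WT vehicle male replicate 2 or WT vehicle male replicate 3, and 1 without HT vehicle male replicate 2. It gave 34 without HT vehicle male replicate 4, 37 without HT vehicle female replicate 2, 292 without WT vehicle female replicate 4 and 336 without HT vehicle female replicate 1. It gave 856 without WT vehicle male replicate 1, 857 without WT vehicle male replicate 4, 918 without WT vehicle male replicate 5, 979 without WT vehicle female replicate 1 and 1367 without HT vehicle female replicate 5.

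Fluoxetine, a serotonin reuptake inhibitor, changed 2420 genes on average over the genotypes and sexes. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), which makes the precursor of mevalonate, fell by 0.33 ± 0.036 on the log2 scale (adjusted p = 4.68e-09). The transcriptional corepressor gene Cbfa2t3 fell by 0.59 ± 0.054 (adjusted p = 7.35e-11), and the monocarboxylate transporter gene Slc16a1 by 0.41 ± 0.042 (adjusted p = 1.92e-09). The zinc finger gene Zfp366 (-0.62), Banp (-0.36), the prolyl hydroxylase gene P4ha1 (-0.33), the death receptor gene Tnfrsf25 (-0.93), Fam53b (-0.40), the metal transporter gene Slc39a8 (-0.43) and the stress gene Gadd45a (-0.55) fell too. Nrde2, an RNA surveillance gene (0.34 ± 0.037, adjusted p = 6.57e-09), Lcmt2 (0.41), Lrrc29 (0.70), Mzf1 (0.25), Fam83h (0.45), Atp10d (0.39), the axon guidance gene Slit1 (0.37), the repair gene Brca2 (0.40), the splicing factor gene Cwc22 (0.26) and the lipid droplet gene Plin4 (1.04 ± 0.16) rose. Hmgcs1, Slc16a1 and Slc39a8 were lower in 20 of 20 fluoxetine libraries than the vehicle mean of the same genotype and sex, Cbfa2t3 in 19 of 20, and Nrde2 was higher in 20 of 20. In all, 1241 genes rose and 1179 fell (limma), with a median absolute log2 fold change of 0.18 and 10 genes changed at least 2-fold. The alternatives kept each of the 20 genes with the smallest p-values past the threshold.

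Of 25 cholesterol genes, 17 fell with fluoxetine, among them Hmgcs1, Sqle (-0.24), Sc5d (-0.22), Idi1 (-0.36) and Msmo1 (-0.34), and 1 rose; 18 fell and 1 rose adjusted over the list alone (camera, adjusted p = 3.45e-15; adjusted p = 0.258 with an estimated correlation). Of 32 immediate early genes, 15 fell, among them Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984; -0.68 ± 0.089, adjusted p = 6.82e-07), Egr2 (-1.18), Nr4a3 (-0.78), Fos (-0.80) and Dusp6 (-0.36), and 19 fell and 1 rose adjusted over the list alone (camera, adjusted p = 1.27e-09; adjusted p = 0.451 with an estimated correlation). Egr1 was lower in 17 of 20 libraries and in 3 of the 4 strata. Of 18 clock genes, 7 fell, among them Bhlhe40 (-0.47), Per2 (-0.34), Nr1d1 (-0.38) and Arntl (-0.21), and 1 rose; 8 fell and 1 rose adjusted over the list alone (camera, adjusted p = 7.62e-05; adjusted p = 0.264 with an estimated correlation). Glucocorticoid-responsive genes were higher, with 7 risen, among them Plin4, Hif3a (0.62), the co-chaperone gene Fkbp5 (0.50) and Sult1a1 (0.48), and 1 fallen, and 10 risen and 3 fallen adjusted over the list alone (camera, adjusted p = 0.0017; adjusted p = 0.629 with an estimated correlation). Of 20 endothelial markers, 6 fell, among them the receptor gene Flt1 (-0.35), Rgs5 (-0.33) and Cldn5 (-0.24), and 1 rose, with the same numbers adjusted over the list alone (camera, adjusted p = 0.000555; adjusted p = 0.592 with an estimated correlation). Of the serotonin list of 18, the receptor genes Htr1a (0.22) and Htr2a (0.22) rose, over all genes and adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.56). By stratum, the mean of the immediate early list was higher with fluoxetine in HT females (0.321) and lower in HT males (-0.488), WT females (-0.719) and WT males (-0.353). That of the glucocorticoid list was -0.0307, 0.207, 0.495 and 0.144 in the same order, and that of the endothelial markers -0.0526, -0.0773, -0.257 and -0.041.

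Ribosomal genes were higher with fluoxetine, with 14 risen and 19 adjusted over the list alone (camera, adjusted p = 4.03e-10; adjusted p = 0.643 with an estimated correlation), and genes of oxidative phosphorylation with 11 risen over all genes and adjusted over the list alone (adjusted p = 2.23e-07; adjusted p = 0.692 with an estimated correlation). In HT females, HT males, WT females and WT males the ribosomal mean differed by 0.0491, 0.236, -0.0988 and 0.205 and that of oxidative phosphorylation by -0.0268, 0.14, -0.0553 and 0.215, so the latter was higher in males alone. The histone methyltransferase gene Kmt2a (-0.25) and the demethylase gene Kdm2a (-0.15) fell, Kdm6a (0.16) rose, and the chromatin list with 2 risen and 2 fallen, over all genes and adjusted over the list alone, did not pass (camera, adjusted p = 0.14). Striatal markers were higher with a median of 0.30 and none passing (camera, adjusted p = 0.0272; adjusted p = 0.873 with an estimated correlation), which rested on WT males (difference of list means 1.21; 0.351 over the 4 strata and 0.0664 without WT males). Mitochondrially encoded genes were lower (camera, adjusted p = 0.0436; adjusted p = 0.849 with an estimated correlation), with 1 of 13 fallen over all genes and adjusted over the list alone, and higher in HT males (0.228). The log2 fold changes had a Spearman correlation with GC content of 0.235 across genes.

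In HT males fluoxetine gave the most calls of the 4 strata, with 462 genes risen and 564 fallen (limma). Hmgcs1 (-0.54 ± 0.072, adjusted p = 8.1e-06), Cbfa2t3 (-0.68), the kinase gene Sik2 (-0.52), Nr4a3 (-1.23), P4ha1 (-0.47), Sc5d (-0.37), Lims1 (-0.42), Cpd (-0.28), the inositol kinase gene Ipmk (-0.37) and the glycolysis gene Pfkfb3 (-0.49) fell. Lrrc29 (1.13 ± 0.19, adjusted p = 0.000568), Snhg20 (0.67), Spaca6 (0.52), Nrde2 (0.41), Mzf1 (0.39), AI480526 (0.62), Zfp512b (0.35), Ppib (0.27) and the ribosomal genes Rpl32 (0.36) and Rps21 (0.46) rose. Cholesterol genes had 13 fallen and 18 adjusted over the list alone (camera, adjusted p = 3.58e-14; adjusted p = 0.258 with an estimated correlation). Immediate early genes had 8 fallen, among them Egr1 (-0.96), Egr2 (-1.67) and Fos (-1.21), and 12 adjusted over the list alone (camera, adjusted p = 9.53e-09; adjusted p = 0.451 with an estimated correlation). Clock genes had 5 fallen, among them Per2 (-0.54), and 1 risen, with 6 and 1 adjusted over the list alone (camera, adjusted p = 0.00291; adjusted p = 0.451 with an estimated correlation). Ribosomal genes had 10 risen and 45 adjusted over the list alone (camera, adjusted p = 3.25e-19; adjusted p = 0.451 with an estimated correlation). Unfolded protein genes had 2 fallen and 3 adjusted over the list alone (camera, adjusted p = 0.00717; adjusted p = 0.643 with an estimated correlation). The count of 1026 was 222 without HT fluoxetine male replicate 4, 475 without HT vehicle male replicate 3, 667 without HT fluoxetine male replicate 3 and 676 without HT vehicle male replicate 2.

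In WT females 509 genes changed with fluoxetine. Fkbp5 (1.14 ± 0.19, adjusted p = 0.00021), Hif3a (1.34), Plin4 (1.84 ± 0.33, adjusted p = 0.000508), Nrde2 (0.47), Lcmt2 (0.58), Wipf3 (0.48), Pkdrej (1.06), Sf3b1 (0.36) and Brca2 (0.66) rose. Cbfa2t3 (-0.84 ± 0.11, adjusted p = 4.18e-06), Tnfrsf25 (-1.72), the progenitor gene Sox21 (-0.83), Slc16a1 (-0.59), Egr2 (-2.33 ± 0.34), Egr1 (-1.21 ± 0.18), Ackr3 (-0.60), Icam2 (-0.92), Zfp366 (-0.85) and Bhlhe40 (-0.80) fell. Of the immediate early genes 14 fell, among them Fos (-1.74) and Arc (-2.24), and 19 adjusted over the list alone (camera, adjusted p = 1.29e-18; adjusted p = 0.258 with an estimated correlation). Of the glucocorticoid list 7 rose and Per1 (-0.67) fell, with 14 risen and 1 fallen adjusted over the list alone (camera, adjusted p = 1.56e-08; adjusted p = 0.359 with an estimated correlation). Cholesterol genes had 8 fallen and 11 adjusted over the list alone (camera, adjusted p = 4.6e-10; adjusted p = 0.375 with an estimated correlation). Of the endothelial markers Flt1 (-0.54), Cldn5 (-0.68) and Tek (-0.49) fell, and 7 adjusted over the list alone (camera, adjusted p = 4.27e-08; adjusted p = 0.375 with an estimated correlation). The serotonin receptor genes Htr1f (0.83) and Htr2a (0.53) rose over all genes and adjusted over the list alone, and their list did not pass (camera, adjusted p = 0.684; its median and mean were below 0 and its test pointed up). Mitochondrially encoded genes stood at a mean log2 of 15.89 (lowest library 15.81) with vehicle, the highest of the 12 groups, and 15.36 (highest library 15.68) with fluoxetine, and 2 of 13 fell adjusted over the list alone (camera, adjusted p = 5.77e-05; adjusted p = 0.517 with an estimated correlation). In all 224 genes rose and 285 fell (limma). The count of 509 was 303, 326 and 322 without WT fluoxetine female replicates 3, 4 and 5, and 318 without WT vehicle female replicate 4. HT males and WT females share no library, and 146 genes were called in both, 45 risen (5.79 by chance) and 101 fallen (8.99 by chance), with 0 in opposite directions.

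In WT males 152 genes changed with fluoxetine. Ndufa4 (0.46 ± 0.093, adjusted p = 0.0149), Ndufs4 (0.35), Ndufaf5 (0.32), Lcmt2 (0.57 ± 0.10, adjusted p = 0.00577), Spcs1 (0.40), Snrpe (0.46) and the differentiation inhibitor gene Id2 (0.37) rose. Kmt2d (-0.53 ± 0.10, adjusted p = 0.011), Kmt2a (-0.46), Baz1b (-0.22), Myh9 (-0.46), Mirg (-0.52), Banp (-0.39), Zfp366 (-0.64) and Per2 (-0.46) fell. Oxidative phosphorylation had 8 risen and 45 adjusted over the list alone (camera, adjusted p = 1.15e-26; adjusted p = 0.326 with an estimated correlation), and ribosomal genes 1 and 33 (adjusted p = 3.97e-19; adjusted p = 0.451 with an estimated correlation). The chromatin list had 4 fallen, and 11 fallen and 1 risen adjusted over the list alone (camera, adjusted p = 7.47e-08; adjusted p = 0.375 with an estimated correlation). The Wnt list had Lef1 (-0.62) fallen and 3 adjusted over the list alone (camera, adjusted p = 0.00163; adjusted p = 0.258 with an estimated correlation). Immediate early genes were lower (camera, adjusted p = 1.15e-05; adjusted p = 0.629 with an estimated correlation), with none fallen over all genes and 5 adjusted over the list alone. Striatal markers were higher with a median of 0.85 and 7 risen adjusted over the list alone (camera, adjusted p = 2.62e-08; adjusted p = 0.629 with an estimated correlation), and olfactory bulb markers lower with a median of -0.89 and none passing (adjusted p = 0.0114; adjusted p = 0.854 with an estimated correlation). WT vehicle male replicate 2, low for ribosomal genes (10.71), is in this comparison. In all 74 genes rose and 78 fell (limma). The count of 152 was 26 without WT vehicle male replicate 2, 54 without WT vehicle male replicate 3 and 378 without WT vehicle male replicate 5. It was 32, 40, 85, 41 and 64 without WT fluoxetine male replicates 1, 2, 3, 4 and 5.

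In HT females limma called 0 genes for fluoxetine, with 1370 at an unadjusted p under 0.05, 0 called by edgeR and 5 by DESeq2, and 2 called by limma without HT fluoxetine female replicate 2. The ceramidase gene Acer2 (-0.96 ± 0.19, adjusted p = 0.0768), Sar1b (-0.41, adjusted p = 0.216) and C1d (-0.44, adjusted p = 0.216) had the smallest p-values. Cholesterol genes were lower as a list (camera, adjusted p = 8.89e-07; adjusted p = 0.451 with an estimated correlation), with none fallen over all genes and 5 adjusted over the list alone. Immediate early genes were higher with a median of 0.30 and none passing (camera, adjusted p = 7.72e-06; adjusted p = 0.627 with an estimated correlation). The genotype by fluoxetine interaction had 3 genes positive and 4 negative (limma), among them the riboflavin kinase gene Rfk (-0.33, adjusted p = 0.031), Mirg (0.50), C1d (-0.49), Gas8 (0.35), the actin-severing gene Cfl2 (-0.39) and 1110059E24Rik (-0.47). With the trends of GC content and length removed limma called 0 (1894 at an unadjusted p under 0.05), and on all libraries without removal edgeR called 4 and DESeq2 116; leaving out any 1 of 34 of the 40 libraries moved the count of 7 by more than 1.5 times, from 0 to 207 (207 without WT vehicle male replicate 2).

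**Figure D2:**
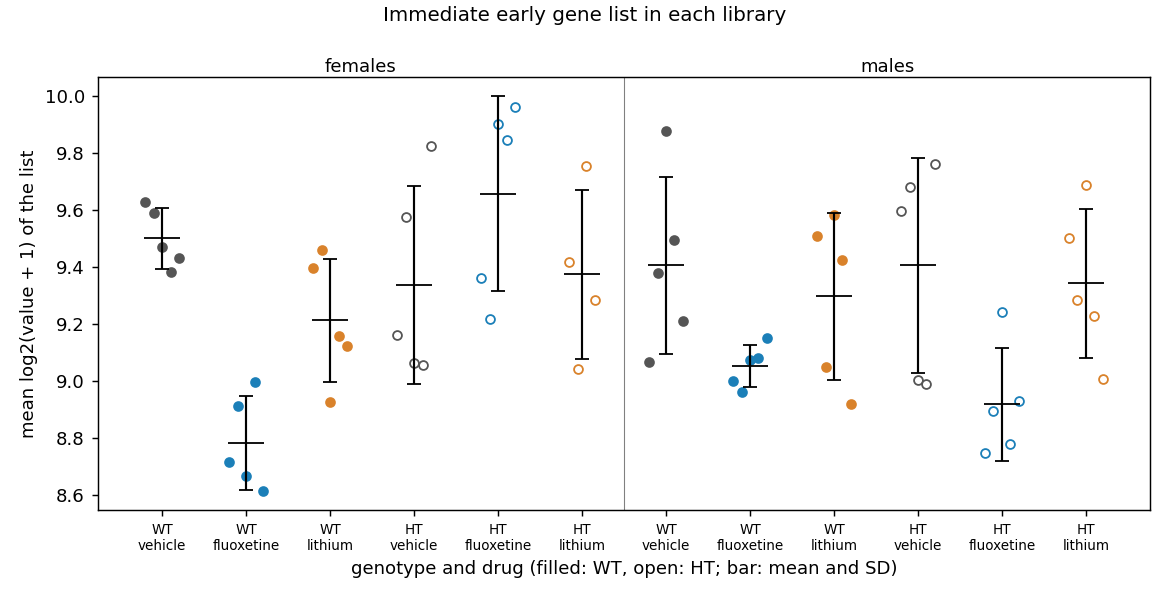
Mean log2 normalised read count of the 32 immediate early genes in each library, by genotype, drug and sex, with the mean and SD of each group. WT females lie at 9.5 with vehicle and 8.78 with fluoxetine, HT males at 9.41 and 8.92, and HT females at 9.34 and 9.66.

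The sex by fluoxetine interaction was negative for 67 genes and positive for 9 (limma). The respiratory chain genes Ndufs4 (-0.42), Ndufa5 (-0.45), Cox7a2 (-0.40) and Ndufa4 (-0.49) and the translocon gene Ssr4 (-0.39) had lower changes in females, and the phosphodiesterase-anchoring gene Pde4dip (0.34) a higher change, each with adjusted p = 0.00623. With the trends of GC content and length removed, 6 genes were called and the calls of Ndufa5, Cox7a2, Pde4dip and Ndufa4 ended. The log2 differences had a Spearman correlation of 0.371 with gene length across genes. The count of 76 was 48 without HT fluoxetine female replicate 4, 49 and 44 without HT vehicle female replicates 2 and 4, and 50 and 36 without HT vehicle male replicates 3 and 5. It was 41 and 44 without WT fluoxetine female replicates 2 and 5, 45 and 38 without WT fluoxetine male replicates 1 and 2, 36 and 39 without WT vehicle female replicates 3 and 4, and 121 without WT vehicle male replicate 5.

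Lithium changed 2347 genes on average over the genotypes and sexes. Ctnnb1, which encodes beta-catenin, fell by 0.22 ± 0.028 on the log2 scale (adjusted p = 6.11e-07). Slc16a1 fell by 0.41 ± 0.043 (adjusted p = 4.49e-09) and the growth factor binding gene Igfbp5 by 0.47 ± 0.058 (adjusted p = 2.14e-07). The Notch-regulated gene Nrarp (-0.38), the meningeal transcription factor gene Foxc1 (-0.45), Rras2 (-0.31), Slc39a8 (-0.43), the urea transporter gene Slc14a1 (-0.46), Frat2 (-0.43), which encodes a binder of glycogen synthase kinase, and the growth factor gene Ptn (-0.32) fell. Dapk1 (0.26 ± 0.030, adjusted p = 1.11e-07), Wipf3 (0.37), Ogdhl (0.32), Tcea2 (0.35), Sgsm1 (0.30), Fam107a (0.43), Lrfn2 (0.39), Mroh1 (0.35), Gba2 (0.22) and the astrocyte reaction gene Serpina3n (0.59 ± 0.078, adjusted p = 7.37e-07) rose. Ctnnb1, Slc16a1, Igfbp5 and Slc39a8 were lower and Serpina3n higher in 19 of 19 lithium libraries than the vehicle mean of the same genotype and sex. In all, 1321 genes rose and 1026 fell (limma), with a median absolute log2 fold change of 0.186 and 9 genes changed at least 2-fold. The alternatives kept each of the 20 genes with the smallest p-values past the threshold.

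Of 24 Wnt genes, 6 fell with lithium, among them Ctnnb1, Lef1 (-0.40), Wif1 (-0.50) and Sfrp1 (-0.26), and 8 adjusted over the list alone (camera, adjusted p = 0.000394; adjusted p = 0.215 with an estimated correlation). Of 67 genes of oxidative phosphorylation, 25 rose, among them Ndufa9 (0.11), and 34 adjusted over the list alone (camera, adjusted p = 1.35e-11; adjusted p = 0.57 with an estimated correlation). Of 28 unfolded protein genes, 12 rose, among them Hyou1 (0.26), Pdia6 (0.21), Sdf2l1 (0.42) and the chaperone gene Hspa5 (0.26), and Slc7a11 (-0.34) fell, with 17 risen and 1 fallen adjusted over the list alone (camera, adjusted p = 3.19e-05; adjusted p = 0.451 with an estimated correlation). Of 20 glucocorticoid-responsive genes, 7 rose, among them Zbtb16 (0.58), Fkbp5 (0.64) and Plin4 (1.04), and Errfi1 (-0.18) fell, with 8 and 1 adjusted over the list alone (camera, adjusted p = 0.00133; adjusted p = 0.627 with an estimated correlation). Of the inositol list, which holds the lithium target gene Impa1, Cdipt (0.19), Impa1 (0.17) and Ppip5k1 (0.14) rose over all genes and adjusted over the list alone (camera, adjusted p = 0.0436; adjusted p = 0.451 with an estimated correlation). Of the cholesterol genes 7 fell, among them Hmgcs1 (-0.19) and Insig1 (-0.22), and 9 fell and 1 rose adjusted over the list alone (camera, adjusted p = 3.04e-05; adjusted p = 0.57 with an estimated correlation). Of the list of immature neurons Marcksl1 (-0.25), Neurog2 (-0.53) and Tmsb10 (-0.20) fell, and 4 adjusted over the list alone (camera, adjusted p = 0.00176; adjusted p = 0.601 with an estimated correlation). The mean of oxidative phosphorylation was lower in WT females (-0.089), against 0.131, 0.139 and 0.172 in HT females, HT males and WT males, and that of the cholesterol genes higher in HT females (0.0443).

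Of 19 meningeal markers, 8 fell with lithium, among them Bgn (-0.36), Col3a1 (-0.38) and Dcn (-0.38), and 12 adjusted over the list alone (camera, adjusted p = 8.89e-07; adjusted p = 0.588 with an estimated correlation). The call of Dcn ended with covariates for tissue of neighbouring regions. Cell type lists moved both ways. The water channel gene Aqp4 (-0.42) fell while the astrocyte genes Gjb6 (0.30) and Aldoc (0.20) rose, with 2 risen and 5 fallen, and 2 and 6 adjusted over the list alone (camera, adjusted p = 0.117). The microglial receptor gene P2ry12 (-0.38) was 1 of 4 fallen markers of microglia, and 1 rose, with the same numbers adjusted over the list alone (adjusted p = 0.0527). The neuropeptide gene Vgf (0.49) was 1 of 5 risen neuropeptide genes, and 4 fell, with 6 and 5 adjusted over the list alone (adjusted p = 0.117). Of the inhibitory neuron markers Pvalb (0.38) rose and Crh (-0.27) and Erbb4 (-0.15) fell, over all genes and adjusted over the list alone (adjusted p = 0.228). Kdm6a fell with lithium (-0.21) and Per2 rose (0.16), each opposite to its change with fluoxetine. Striatal markers were higher with a median of 0.36 (camera, adjusted p = 0.00475; adjusted p = 0.873 with an estimated correlation) and olfactory bulb markers lower with a median of -0.48 (adjusted p = 0.0394; adjusted p = 0.873 with an estimated correlation), none passing, though olfactory bulb markers were higher in WT females (0.888). The log2 fold changes had a Spearman correlation with GC content of 0.204 across genes.

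In HT females 325 genes rose and 207 fell with lithium (limma, 4 against 5 libraries). The metabolic gene Gpd1 (0.45 ± 0.079, adjusted p = 0.0113), the phosphoinositide gene Cdipt (0.30), Pik3cd (0.47), Tcea2 (0.45), B4galnt1 (0.47), Ptp4a3 (0.41), Plbd2 (0.46), Phkg2 (0.26) and Ppp6r1 (0.31) rose. Thsd7a (-0.64), Slc16a1 (-0.46), Rimklb (-0.37), Kdm6a (-0.36), the kinase gene Yes1 (-0.72), the ephrin receptor gene Epha3 (-0.82) and Foxc1 (-0.56) fell. Oxidative phosphorylation had 5 risen and 16 adjusted over the list alone (camera, adjusted p = 4.32e-09; adjusted p = 0.629 with an estimated correlation). The thyroid list had Hr (0.52) and the neurofilament gene Nefh (0.53) risen, and 6 adjusted over the list alone (adjusted p = 0.0111; adjusted p = 0.451 with an estimated correlation). Meningeal markers had Dcn (-0.78) fallen and 7 adjusted over the list alone (adjusted p = 5.33e-07; adjusted p = 0.588 with an estimated correlation). Olfactory bulb markers were lower with a median of -1.15 and none passing (adjusted p = 0.000842; adjusted p = 0.796 with an estimated correlation). The log2 fold changes had a Spearman correlation with GC content of 0.481 across genes, and 14 genes were called after its removal with that of length. The count of 532 was 0 without HT lithium female replicate 3, HT vehicle female replicate 2 or HT vehicle female replicate 4, 100 and 55 without HT lithium female replicates 1 and 2, and 935 without HT vehicle female replicate 5; with all libraries edgeR called 559 and DESeq2 1035, and 3631 had an unadjusted p under 0.05.

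In HT males 25 genes rose and 20 fell with lithium (limma). Serpina3n (0.88 ± 0.15, adjusted p = 0.00231), AI854703 (0.41), Tcea2 (0.47), the redox gene Srxn1 (0.31), Fam107a (0.55), Unc79 (0.28), Ogdhl (0.35) and Hspb7 (1.14) rose. Nrarp (-0.59 ± 0.098, adjusted p = 0.00208), Ctnnb1 (-0.31), Slc16a1 (-0.50), Igfbp5 (-0.63), Ptn (-0.47), the collagen crosslinking gene Lox (-0.93), Frat2 (-0.56) and Marcks (-0.43) fell. The Wnt list had Ctnnb1 fallen and 3 adjusted over the list alone (camera, adjusted p = 0.00305; adjusted p = 0.264 with an estimated correlation). Unfolded protein genes had 6 risen and 1 fallen adjusted over the list alone (adjusted p = 1.72e-05). So adjusted, oxidative phosphorylation had 5 risen (adjusted p = 1.85e-15) and cholesterol 8 fallen (adjusted p = 8.54e-08). Each had none over all genes and a camera adjusted p of 0.451 with an estimated correlation. The count of 45 was 12 and 21 without HT lithium male replicates 2 and 3, and 12, 14 and 15 without HT vehicle male replicates 1, 2 and 5.

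In WT females 314 genes rose and 124 fell with lithium (limma). Of these, 183 rose and 41 fell in HT against WT vehicle females too, with 0 opposite (Pearson's r across genes 0.638). Both comparisons subtract the same WT vehicle libraries, so the shared calls are not independent. Dapk1 (0.37 ± 0.060, adjusted p = 0.00187), the histone ubiquitin ligase gene Rnf20 (0.29), Wipf3 (0.48), Txndc16 (0.34), Unc79 (0.32), Sf3b1 (0.38), Zbtb16 (0.82 ± 0.16, adjusted p = 0.00497), Lyst (0.48) and Pcmtd2 (0.40) rose. Slc39a8 (-0.58 ± 0.11, adjusted p = 0.00497), Camk2n2 (-0.44), Slc16a1 (-0.42), Mecom (-0.59) and the tight junction gene Cldn5 (-0.56) fell. Ribosomal genes had 8 fallen and 42 adjusted over the list alone (camera, adjusted p = 1.04e-20; adjusted p = 0.451 with an estimated correlation). Endothelial markers had 3 fallen and 12 adjusted over the list alone (adjusted p = 2.73e-09; adjusted p = 0.326 with an estimated correlation). Autism risk genes had 4 risen and 9 adjusted over the list alone (adjusted p = 1.15e-07; adjusted p = 0.553 with an estimated correlation). Of the glucocorticoid list Zbtb16, Fkbp5 (0.90) and Hif3a (1.02) rose, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.00309; adjusted p = 0.643 with an estimated correlation). Cholesterol genes had 1 fallen and 10 adjusted over the list alone (adjusted p = 4.97e-08). Markers of microglia had none and 3 (adjusted p = 5.33e-07). With an estimated correlation each camera adjusted p was 0.451. Oxidative phosphorylation was lower as a list (adjusted p = 0.000113; adjusted p = 0.849 with an estimated correlation) while Ndufs1 (0.29) rose, over all genes and adjusted over the list alone, and with the GC content and length trends removed the direction of the list turned (adjusted p = 0.973). Mitochondrially encoded genes stood at a mean log2 of 15.89 with vehicle and 15.4 (highest library 15.55) with lithium, none passing (camera, adjusted p = 0.000414; adjusted p = 0.588 with an estimated correlation). The log2 fold changes had a Spearman correlation with GC content of -0.37 across genes. The count of 438 was 166, 72, 228, 187 and 123 without WT lithium female replicates 1, 2, 3, 4 and 5, and 49, 165 and 695 without WT vehicle female replicates 3, 4 and 5.

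In WT males 52 genes rose and 33 fell with lithium (limma). Ogdhl (0.48 ± 0.077, adjusted p = 0.00121), Serinc2 (0.98), Tmed9 (0.33), the histocompatibility gene H2-T23 (0.49), Lrfn2 (0.51), the erythropoietin receptor gene Epor (0.85) and Clstn3 (0.46) rose. Kdm6a (-0.40 ± 0.067, adjusted p = 0.0017), Bin2 (-0.61), Ptn (-0.42), the adhesion gene Nectin3 (-0.66), Frat2 (-0.54) and the deacetylase gene Sirt1 (-0.45) fell. Oxidative phosphorylation had none risen over all genes and 38 adjusted over the list alone (camera, adjusted p = 1.11e-18; adjusted p = 0.451 with an estimated correlation). The chromatin list had Kdm6a fallen and 4 adjusted over the list alone (adjusted p = 6.58e-06; adjusted p = 0.451 with an estimated correlation). Of the glucocorticoid list Fkbp5 (0.78) rose and Errfi1 (-0.32) fell, with 5 and 1 adjusted over the list alone (adjusted p = 0.128). Striatal markers were higher with a median of 0.54 and none passing (adjusted p = 0.000855; adjusted p = 0.852 with an estimated correlation). The count of 85 was 10, 20, 3, 13 and 156 without WT lithium male replicates 1, 2, 3, 4 and 5, and 134, 4, 26 and 205 without WT vehicle male replicates 1, 2, 3 and 5.

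Genes called with lithium were compared between strata that share no library. The values by chance treat genes as independent, so a larger overlap is not by itself evidence of a common effect. HT and WT males had 9 genes in both, 4 risen (0.0727 by chance) and 5 fallen (0.0369 by chance). HT females and HT males had 16, 6 risen (0.455 by chance) and 10 fallen (0.232 by chance). HT and WT females had 15, 5 risen (5.71 by chance), 3 fallen (1.44 by chance) and 7 in opposite directions, and WT females and WT males had 5, 3 risen (0.913 by chance) and 2 fallen (0.229 by chance). Pearson's r of the lithium log2 fold changes across genes, which are not independent replicates, was 0.313, 0.307, -0.166 and -0.0119 in the same order. The genotype by lithium interaction had 0 genes called by limma, with 1700 at an unadjusted p under 0.05, 0 called by edgeR and 5 by DESeq2. The sex by lithium interaction had 0 called by limma, with 1041 at an unadjusted p under 0.05, 0 called by edgeR and 2 by DESeq2.

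**Figure D3:**
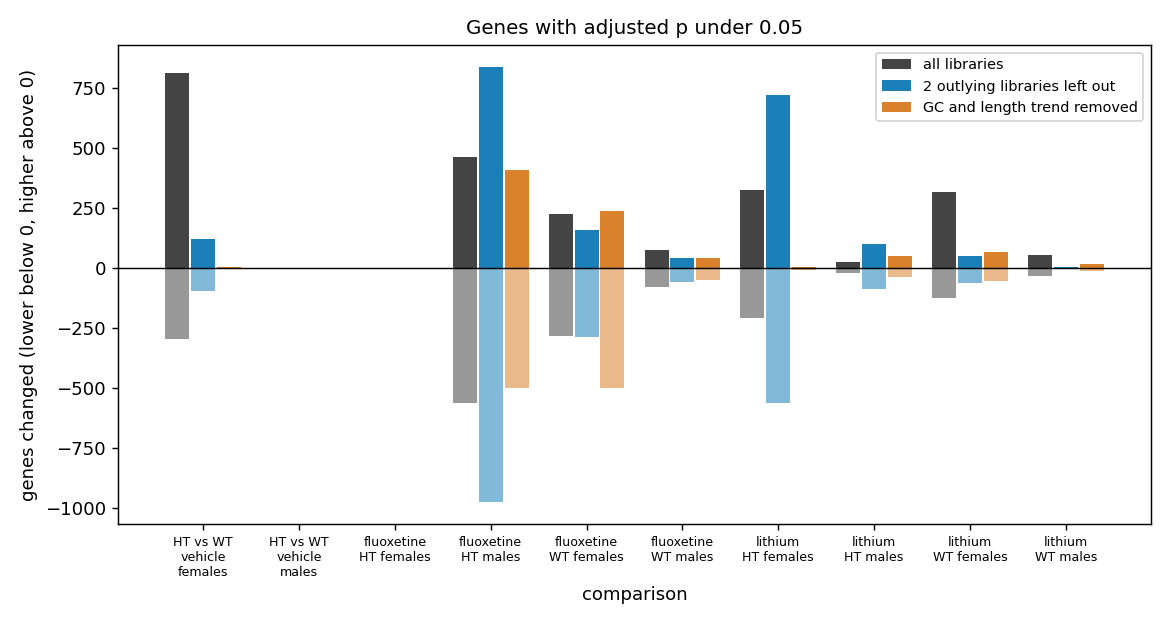
Number of genes higher and lower at an adjusted p under 0.05 in limma for the 10 comparisons within a drug or a genotype and sex, with all libraries, without the 2 libraries of low weight, and with the trends of GC content and length removed. HT against WT vehicle females gives 1109, 216 and 7 genes, and fluoxetine in HT males 1026, 1809 and 908.

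Whether a drug moved genes against the genotype difference was examined across all genes tested, and the same HT vehicle libraries enter both sides of such a correlation. For fluoxetine in HT mice against HT versus WT vehicle, Pearson's r was -0.406 in females and -0.306 in males. Random draws of libraries with the group means removed gave -0.49 ± 0.117 (SD) and -0.499 ± 0.107 from the shared libraries alone. The covariances were -0.0319 and -0.024 against values in the draws of -0.0312 and -0.0326, and with the HT vehicle libraries split between the 2 sides, r was 0.00117 and 0.0513. For lithium, r was -0.621 in females and -0.274 in males, against -0.453 ± 0.121 and -0.507 ± 0.0982 in the draws. The covariances were -0.0645 and -0.0199 against -0.031 and -0.0325, and the split r was -0.228 and 0.0921. In females 8 of 100 draws were as low as the lithium r, and 5 of 100 as far from 0 as its split r.

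The changes with fluoxetine and with lithium were compared in the same way, and they share the vehicle libraries of their stratum. Pearson's r across genes was 0.375 in HT females (simulated 0.462; split 0.00938), 0.483 in HT males (0.476; 0.112), 0.565 in WT females (0.494; 0.13) and 0.598 in WT males (0.491; 0.116). The covariances were 0.0322, 0.0437, 0.0515 and 0.0535 in the same order, against simulated values of 0.0317, 0.0304, 0.0315 and 0.0318.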

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

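The tests of the count in vehicle females, of the Ash1l level of WT vehicle female replicate 3, and of litter or handling for the immediate early genes were chosen after the result was seen, as were the exact permutation tests of list means.

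Each of 12 groups was examined in 8 measures, 96 sets in all, for a library whose gap to the nearest other, divided by the range, exceeded Dixon's critical value; 12 sets had one, where that value lets chance give about 1 in 20. Log2 Ash1l was 11.8 in WT vehicle female replicate 3 (others of its group 12.2 to 12.3). It was 11.97 in HT fluoxetine female replicate 1 (11.92 to 11.94). The mean log2 level of 19 striatal markers was 9.08 in HT lithium male replicate 4 (others 6.545 to 6.72), 8.85 in WT lithium female replicate 4 (6.387 to 6.68) and 8.575 in WT fluoxetine female replicate 3 (6.503 to 6.806). It was 8.558 in WT vehicle female replicate 3 (6.458 to 6.475), 8.261 in HT vehicle male replicate 5 (6.465 to 6.571), 7.761 in HT fluoxetine male replicate 5 (6.403 to 6.624) and 7.581 in HT fluoxetine female replicate 1 (6.442 to 6.709). The choroid plexus markers stood at 7.35 in WT vehicle female replicate 3 (4.318 to 5.008). Genes of oxidative phosphorylation stood at 11.32 in WT lithium male replicate 1 (11.1 to 11.14), and ribosomal genes at 10.71 in WT vehicle male replicate 2 (11.04 to 11.11).

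The interaction test called 519 genes for genotype by sex in vehicle mice, 7 for genotype by fluoxetine and 76 for sex by fluoxetine. Of 315 exact 2-sided permutation tests of differences in list means between strata, 5 passed after Benjamini-Hochberg adjustment and 44 had an exact p under 0.05. With lithium the mean of thyroid-responsive genes went from 10.70 to 10.87 in HT females and from 10.83 to 10.73 in WT females, a difference of 0.272 (exact permutation p = 3.15e-05, adjusted p = 0.00992), and with GC content and length trends removed it was 0.166 (exact p = 0.0011). In HT males it went from 10.82 to 10.76, a difference of 0.227 from HT females (adjusted p = 0.0149), and 0.159 with the trends removed (exact p = 0.00123). With lithium, autism risk genes differed between HT and WT females by -0.229 and genes of GABA receptors by -0.244 (each adjusted p = 0.0298); with the trends removed the exact p was 0.112 and 0.094. With fluoxetine, glutamate receptor genes differed between WT females and males by 0.212 (adjusted p = 0.0298; exact p = 0.176 with the trends removed). Without WT vehicle female replicate 3 and WT vehicle male replicate 2 the autism, GABA and glutamate differences shrank to -0.155, -0.164 and 0.117 (exact p = 0.00151, 0.00107 and 0.00125), and the thyroid difference between HT and WT females was 0.264 (exact p = 6.3e-05).

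Heterozygosity gave 1109 genes in vehicle females and 1 in vehicle males. With covariates for markers of neighbouring regions, 1145 genes were called, so tissue of those regions was not the whole of it. Without WT vehicle female replicate 3 the count was 20, and with the trends of GC content and length removed it was 7; over the 1109 genes the median absolute log2 fold change went from 0.33 (median SE 0.0896) to 0.249 (0.0876) and 0.16 (0.0723), so the calls ended because the changes shrank. That library and the trend are candidate sources of most calls. The Spearman correlation of deviations with GC content was 0.331 in it. It was -0.536 in HT vehicle female replicate 4, -0.302 to -0.273 in HT replicates 1 to 3 and 0.248 in HT replicate 5. A smaller effect of genotype in females stays open. Of 100 splits of the libraries 3 gave as many genes as the real 1109, the real one included, and the highest other gave 1604. Chance is excluded only by the threshold of 5 set beforehand, which was not corrected for the number of results it was applied to. Splits that called more genes than the real one occurred, so this exclusion is weak.

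Immediate early genes were lower with fluoxetine in WT females and HT males. The difference of the list mean was -0.719 in WT females (exact 2-sided permutation p = 0.00794, the smallest that 5 against 5 can give) and -0.488 in HT males (exact p = 0.0476), and neither passed adjustment over 370 such tests, where the smallest adjusted p was 0.117. Removal of the GC content and length trends kept at least 100.8% of each difference and covariates for neighbouring regions kept at least 94.95%, which argues against either as the whole cause. Vehicle groups differed by at most 0.1636 (lowest exact p = 0.333), but litter, day and handling were not labelled, so they cannot be told apart from the drug, and an effect of fluoxetine stays open as a hypothesis.

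Ash1l in WT vehicle female replicate 3 lay among the HT libraries. A score of the other genes that differed by genotype stood at 0.1118 in that library (0.0446 with the trends removed). This was near the HT mean (0.117, SD 0.0796, range -0.0411 to 0.29). It was far above the mean of the other WT libraries (-0.118, SD 0.0881), but within their range (-0.252 to 0.143). So this score leans to HT but cannot tell a mislabelled HT library from a WT library with low Ash1l. Against a mislabelled library stands Tbx1, examined only afterwards, at a normalised count of 62.4 (85 reads) in it, the highest of 59, with 0 to 28.5 in the HT libraries. With the GC content and length trends removed the library's log2 Ash1l was 12.15. This lay between the highest HT (12.11) and lowest other WT library (12.18), which leaves the trend open too. No biological explanation was tested.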

How the results depend on the processing

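edgeR, DESeq2, leaving out WT vehicle female replicate 3 and WT vehicle male replicate 2, removal of trends with GC content and length, and covariates for neighbouring regions were chosen after seeing the data; the other alternatives were fixed before. Except where stated, the cause of a difference was not tested.

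The average effects of fluoxetine and lithium stayed within 1.5 times of their counts under every alternative run, and Ash1l kept its direction and its side of the threshold in the genotype average. TMM scaling and edgeR moved 1 count out of that range, the genotype by fluoxetine interaction, to 4 each. A pseudocount of 10 and no filter moved none.

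Libraries weighted by quality gave 1797 genes for genotype in vehicle females. For fluoxetine they gave 1 in HT females, 1732 in HT males, 1154 in WT females and 396 in WT males, and for lithium 2854, 412, 1215 and 46 in the same order. They gave 117 for the genotype average, 34 for sex, 93 for genotype by sex, 865 for genotype by fluoxetine, 45 for sex by fluoxetine and 256 for genotype by lithium, and Ash1l passed in vehicle females at -0.19.

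A fit of the 2 groups compared gave 0 genes for genotype in females and in males and 0 for fluoxetine in WT males, with 2964, 657 and 2133 at an unadjusted p under 0.05 (limma). It gave 220 for fluoxetine in HT males and 201 in WT females, and for lithium 295 in HT females, 28 in HT males, 8 in WT females and 1 in WT males. Ash1l in vehicle males stayed at -0.40 with an adjusted p of 0.814 in this fit, against 1.11e-09 to 0.000815 in the others.

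DESeq2 called 1701 genes for genotype in vehicle females and 2 in males, 5 for fluoxetine in HT females and 468 in WT males. For lithium it called 1035 in HT females, 169 in HT males, 878 in WT females and 274 in WT males. It called 104 for the genotype average, 58 for sex, 1196 for genotype by sex, 116 for genotype by fluoxetine, 178 for sex by fluoxetine, 5 for genotype by lithium and 2 for sex by lithium. On simulated data, with each gene drawn independently, its false calls in the comparison of vehicle females were 11, against 4 with limma.

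Without both outlying libraries, limma called 216 genes for genotype in vehicle females, with Ash1l at -0.20 and past the threshold. It called 1 for fluoxetine in HT females, 1809 in HT males and 100 in WT males, and for lithium 1282 in HT females, 187 in HT males, 111 in WT females and 5 in WT males. It called 0 for genotype by sex (2215 at an unadjusted p under 0.05), 77 for genotype by fluoxetine and 27 for sex by fluoxetine.

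With the GC content and length trends removed, limma called 7 genes for genotype in vehicle females, with Ash1l at -0.30 and past the threshold, and 88 for fluoxetine in WT males. For lithium it called 14 in HT females, 89 in HT males, 118 in WT females and 29 in WT males. It called 0 for genotype by sex and for genotype by fluoxetine (1808 and 1894 at an unadjusted p under 0.05) and 6 for sex by fluoxetine. Rpl29 turned to 0.023 for genotype in females and 0.0066 for lithium in WT females, Rps15 to 0.0046 for lithium in WT females, and the oxidative phosphorylation list for lithium in WT females turned, with an adjusted p of 0.973.

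Covariates for neighbouring regions gave 2 genes for genotype in males, 1932 for fluoxetine in HT males, 904 in WT females and 242 in WT males. For lithium they gave 109 in HT females, 200 in HT males and 176 in WT females. They gave 161 for the genotype average, 37 for sex, 963 for genotype by sex and 257 for genotype by fluoxetine.

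Deviations from group means correlated above 0.1 in 54 of 319 same-number pairs. Of 59 libraries, 4 correlated best with their own number, which gave no ground for pairing. The number of HT lithium female replicate 4 was uncertain. With the number as a block, 1 gene was called for fluoxetine in HT females. Of 158 list tests past the threshold, 2 stayed past it with an estimated correlation and 47 with fry, which called 52 in all and tests a list without comparing it with other genes.

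The correlations of drug with genotype effects depended on the shared libraries, and for lithium in females a negative value stayed without them. With the HT vehicle libraries split they were 0.00117 and 0.0513 for fluoxetine in females and males, and -0.228 and 0.0921 for lithium. With the trends removed as well they were 0.0521, 0.0235, -0.168 and 0.0807. Over the upper 0.5 of genes by expression, the HT vehicle libraries were again shared by both sides, and no random draws were made. There the correlations were -0.617 and 0.0537 for fluoxetine, and -0.773 and 0.0720 for lithium, in females and males.

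Leaving out 1 library gave 20 to 2151 genes for genotype in vehicle females and 1 to 2 in males. It gave 0 to 2 for fluoxetine in HT females, 222 to 1329 in HT males, 303 to 552 in WT females and 26 to 378 in WT males, and for lithium 0 to 935, 12 to 49, 49 to 695 and 3 to 205 in the same order. The averages ranged from 45 to 85 for genotype, 1928 to 2993 for fluoxetine, 1971 to 2714 for lithium and 19 to 38 for sex. The interactions ranged from 0 to 1367 for genotype by sex, 0 to 207 for genotype by fluoxetine and 36 to 121 for sex by fluoxetine, and gave 0 for both with lithium. The correlations ranged from -0.525 to -0.305 and -0.379 to -0.245 for fluoxetine in females and males, and from -0.689 to -0.566 and -0.363 to -0.207 for lithium. Ash1l ranged from -0.20 to -0.078 in vehicle females, -0.43 to -0.35 in vehicle males and -0.33 to -0.30 on average.

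Of the other single gene and list results, removal of the trends took 266 past calls below the threshold and brought 54 above it, the fit of 2 groups 280 and 18, leaving out both outlying libraries 182 and 111, and neighbouring-region covariates 102 and 111. Weights took 38 and brought 224, DESeq2 0 and 223, the block 40 and 17, edgeR 32 and 28, TMM 22 and 10, no filter 4 and 0, and the pseudocount 2 and 4. Tbx1 stayed past the threshold with a log2 fold change between -2.06 and -1.14 across alternatives and leave-one-out extremes, the latter with a pseudocount of 10. Each library had 24.47 M reads or more, and what depth limited was not tested.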

Other observations

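The tests of the immediate early genes by genotype in females and of Tbx1 by library were chosen after the result was seen.

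Tbx1, a T-box transcription factor gene of the region deleted in DiGeorge syndrome in people, was not lowered evenly. In 7 of 29 HT libraries it had 0 or 1 recovered reads, in the other 22 it had 11 to 25, and in the 30 WT libraries 19 to 85. The 7 libraries were HT fluoxetine female replicate 2, HT fluoxetine male replicates 2 and 5, HT lithium female replicate 1, HT lithium male replicate 3, HT vehicle female replicate 4 and HT vehicle male replicate 2. Of 36 other genes tested within 1 Mb of Tbx1, limma called 0, with log2 fold changes from -0.124 to 0.151. At least 1 of the 7 was in each HT group, and the cause was not tested.

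Of 659 genes called on average for both fluoxetine and lithium against the same vehicle libraries, 42 moved in opposite directions. The shared vehicle libraries alone make changes in the same direction more frequent. The 288 risen and 329 fallen with both are therefore not by themselves evidence of a common effect. Among the 42, Per2 fell with fluoxetine (-0.34) and rose with lithium (0.16), and Kdm6a rose (0.16) and fell (-0.21). Kdm6a was among genes with a genotype by sex interaction as well.

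A stretch of foreign strain sequence carried along with the Ash1l allele would place called genes near it. Within 20 Mb of Ash1l 1 of 63 other called genes of the genotype average was found, Tchh, against 419 of 17863 genes tested (Fisher's exact test, 2-sided, p = 1, 1 test), which argues against it as a source of the called genes as a set.

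In females the mean of the immediate early list went with fluoxetine from 9.34 to 9.66 in HT mice and from 9.5 to 8.78 in WT mice, a difference of 1.04 (exact permutation p = 0.00261; adjusted p = 0.0915 over 315 tests), and with the trends removed the difference was 0.994 (exact p = 0.00296). The difference passed before adjustment and not after it.

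Other splits of the libraries into groups of the same sizes were used to ask whether chance can be excluded. Chance is called excluded here where fewer than 5 of 100 splits were as large, without correction for the number of results. The splits treat each animal as independent. A difference between litters or dams, which were not labelled, could give the same outcome, so the splits do not separate a drug effect from it. Chance was excluded for fluoxetine in HT males (1026 genes, 1 of 100 splits as large with the real one included, highest other 234), WT females (509, 1, highest other 62) and WT males (152, 1, highest other 19). It was excluded for lithium in HT females (532, 2, highest other 731), HT males (45, 1, highest other 9), WT females (438, 1, highest other 16) and WT males (85, 3, highest other 121). It was excluded for the averages of genotype (64, 1, highest other 5), fluoxetine (2420, 1, highest other 608), lithium (2347, 1, highest other 418) and sex (21, 1, highest other 0), and for the interactions of genotype with sex (519, 1, highest other 91), genotype with fluoxetine (7, 4, highest other 273) and sex with fluoxetine (76, 3, highest other 233). It was not excluded for genotype in vehicle males (1, 9 of 100, highest other 2), where the gene called was Ash1l. Where limma called 0 genes every split is as large, so the splits say nothing of chance for fluoxetine in HT females (100 of 100, highest other 215), genotype by lithium (100, highest other 13) and sex by lithium (100, highest other 2). Those 3 had 1370, 1700 and 1041 genes at an unadjusted p under 0.05, edgeR called 0 in each, and DESeq2 called 5, 5 and 2. For genotype by fluoxetine and sex by fluoxetine the highest other split called several times the real count, and the reason was not tested. For these 2, for lithium in HT females and WT males, and for genotype in vehicle females (1604 against 1109), the exclusion of chance rests only on fewer than 5 of 100 splits being as large. For genotype by sex the count of 519 became 0 without WT vehicle female replicate 3 or without WT vehicle male replicate 2. The splits there do not separate an effect of the groups from single libraries.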
